A study of Mus musculus with 8 samples.

How the data were processed

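CD45-selected immune cells of orthotopic ICC tumours carrying mutant IDH1, grown in C57BL/6 mice, were profiled with droplet-based single-cell 5' RNA sequencing in 8 samples, 4 given AG120, an inhibitor of mutant IDH1, and 4 given vehicle. Groups and replicate numbers were taken from the sample titles. The labels do not say whether each sample came from a separate animal. The p-values of permutation, gene and fry tests below therefore measure the spread between samples. Those of camera with the preset correlation set a list against all other genes. They do not measure how far a list varies between samples. The submitters' processing notes name Cell Ranger, Scanpy 1.7 and the mouse build mm10 (GRCm38).

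The deposited matrix of each sample holds raw UMI counts of 31053 genes in the barcodes that the authors' pipeline called as cells, and these counts were the only values used in the tests. The deposited whole-series matrix, although named as counts, holds the natural log (ln) of 1 plus the UMI count per 100000 UMIs of the barcode. Its 47618172 values were compared with the per-sample counts and 0 differed by more than 1% of the count. It holds 39810 barcodes, those with 200 or more genes and no more than 2500 and carries no cell annotation in the part used here. It served only as an alternative set of barcodes.

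Barcodes with at least 250 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, 40892 of 43359. Doublets were scored with Scrublet within Scanpy 1.11.5 per sample, at an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked under 0.5% of cells, so the expected share with the highest scores was marked instead, 1832 cells (4.48%). Counts per 10000 were log-transformed, 2000 variable genes (without antigen-receptor segments, ribosomal, mitochondrial and sex-linked genes) were scaled and reduced to 30 principal components, and a graph of 15 neighbours was clustered with Leiden (leidenalg 0.10.2) at resolution 1 into 32 clusters. T and NK cells, 6919 in all, were clustered again into 17 clusters. The clusters depended on the last digits of the neighbour distances: the same script under another setting of the linear algebra library gave other clusters, so the setting under which they were first made was fixed. Clusters were named by marker lists fixed before the data were examined, so each name below means a cluster that is like that cell type by its markers. A total of 1082 cells not marked as doublets, in 6 clusters led by markers of more than 1 lineage, were left out, which gave 37978 kept cells. Of these, 131 cells with Elane and Mpo matched no list and stayed unnamed. Regulatory T cell markers outnumbered helper T cell markers in the Cd4 clusters other than the Foxp3 cluster, so these are called Cd4 cluster 6 and Cd4 cluster 11.

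Shares of kept cells were compared with exact two-sided permutation tests over the 70 assignments of 8 samples, where the smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over 25 tests. For genes, UMI counts were summed per sample within a class that had at least 20 cells in at least 3 samples per group, and tested with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood fit, two-sided) at an adjusted p of 0.05. Fold changes are AG120 over Vehicle. Levels are CPM of the class, with the SD over 4 samples, and fold changes carry their SE. Treg and Cd4 cluster 11 had too few samples with 20 cells. Gene lists fixed before the data were examined (31, each with at least 5 measured members) were tested with camera of limma 3.58.1, which compares a list with all other genes, with a preset correlation of 0.01 and adjustment over all 179 tests. Of the 48 calls, 0 held with a correlation estimated from the data. The fry test, which asks whether a list's genes move on balance in 1 direction, called 1 list.

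Genes are named by a rule fixed before the data were examined: genes past the threshold with an average log2 CPM of at least 4 (not predicted genes with Gm or Rik symbols), list members past the threshold, and a panel of 36 immune genes. Which panel genes and which lists without a call are printed, and which list members serve as examples (mostly among those with the smallest p), was chosen after their values were seen. Some panel genes are not reported here. Other genes named outside the rule are said to be chosen that way where they appear. The alternatives were a replicate block, RLE size factors, no filter on low counts, sums thinned to the smallest sample, stricter cells (at least 500 genes and at most 5% mitochondrial UMIs), resolution 2, DESeq2 1.42.0, leaving out each sample, and for shares also doublets kept, the whole-series barcodes, the centred log ratio and edgeR on cell counts. Others were chosen after seeing the data: clusters at resolution 1 from neighbour distances held exactly in whole numbers and named by the same rule (31 clusters, and 15 of T and NK cells, in which Cd4 clusters 6 and 11 were 1 cluster), 6 libraries without Vehicle 1 and AG120 2, and the mono/mac class without clusters 7 and 11, as monocytes alone and as macrophages alone. At resolution 2, macrophage clusters 7 and 17, and cluster 15 from exact distances, had Pf4, a platelet marker, and no macrophage marker among their 10 leading genes.

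The samples held 14129830 to 32821268 UMIs. Intervals on shares of single samples are 95% Wilson intervals, those on CPM of single samples are exact Poisson intervals, and both cover counting error only. The gene test was tried on simulated negative binomial counts, drawn with the mean and dispersion fitted to each real gene and with 200 genes changed by a known fold: 71.6% of genes changed 2-fold were recovered in CD8 T cells, 49.3% in monocytes and macrophages, 39.4% over all cells, and 90.8% to 100% of genes changed 4-fold in the 8 comparisons. At 1.5-fold, 1.5% to 32.3% were recovered, and unchanged genes made up 0.9% (B cells) to 12.5% (neutrophils) of calls, with 8.2% in CD8 T cells and 11.4% in monocytes and macrophages. Genes were drawn independently of each other, so differences between libraries that many genes share were left out.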

Results

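The infiltrate of orthotopic mutant IDH1 ICC tumours was collected from C57BL/6 mice on day 13 after inoculation. Mutant IDH1 makes an oncometabolite that inhibits enzymes dependent on 2-oxoglutarate, and AG120 blocks the mutant enzyme. AG120 was given for 6 days from day 7. Tumours were dissociated, and cells were enriched on a density gradient and then by CD45 selection, steps that can set the shares of cell classes. The 4 Vehicle samples held 15108506, 14129830, 21868188 and 32821268 UMIs (replicates 1 to 4), and the 4 AG120 samples held 26756629, 14437523, 25719347 and 31885732. Median UMIs per passing cell ranged from 2449 to 4241.5. After filtering, 37978 cells were kept.

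Sex-linked transcripts differed between samples within both groups. Xist, the RNA that silences 1 X chromosome in female cells, stood at 1.3 CPM over all kept cells of Vehicle 1, at 53.2 CPM in AG120 2, and between 228.54 and 295.97 CPM in the other 6 samples. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together stood at 126 CPM in Vehicle 1 and 94.3 CPM in AG120 2, and at most 7.01 CPM in the other 6. In AG120 2, among 829 cells of more than 5000 UMIs, 13.6% (95% Wilson interval 11.5% to 16.1%) held only Xist, 41.3% (38% to 44.6%) held only Y-linked UMIs and 1.21% (0.66% to 2.21%) held both. Of such deep cells, 3.28% (2.09% to 5.13%) in Vehicle 2 and 1.88% (1.33% to 2.66%) in AG120 3 held only Y-linked UMIs. The share was at most 0.22% in Vehicle 3, Vehicle 4, AG120 1 and AG120 4. The labels state no sex.

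**Figure D1:**
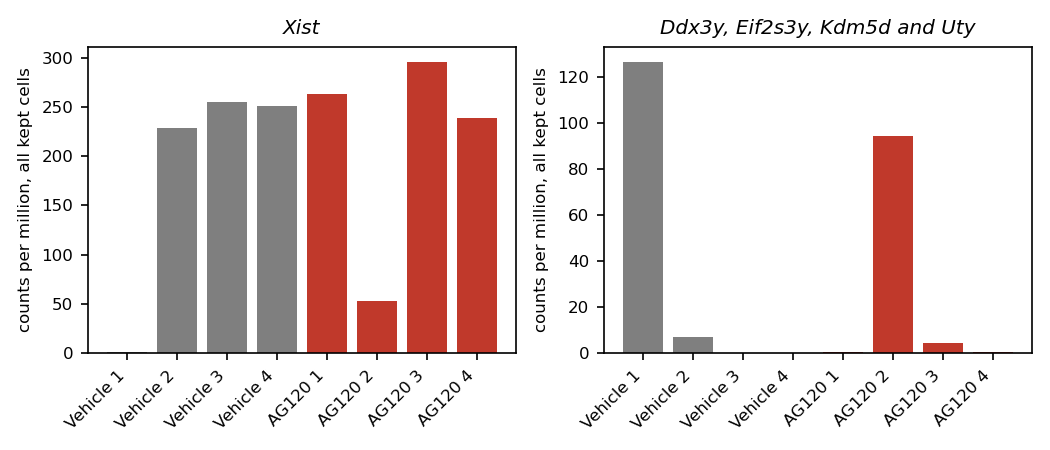
CPM of Xist (left) and of 4 Y-linked genes summed (right) over all kept cells of each sample, 1 bar per sample. Vehicle 1 has 1.3 CPM of Xist and 126 CPM of the Y-linked genes, and AG120 2 has both kinds, at 53.2 and 94.3 CPM.

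The first comparison asked whether blocking mutant IDH1 alters which immune cells are found in the tumour. B cells made up 5.13% ± 2.36 of kept cells in AG120 and 9.45% ± 2.28 in Vehicle (mean ± SD, n = 4; two-sided exact permutation p = 0.0571). Monocytes made up 8.65% ± 4.12 and 15.2% ± 4.39 (n = 4; exact p = 0.0857), and neutrophils 12.1% ± 2.80 and 17.9% ± 5.44 (n = 4; exact p = 0.114). Macrophages made up 38.9% ± 16.3 and 25.1% ± 7.62 (n = 4; exact p = 0.171). CD8 T cells, the main killers of tumour cells, made up 11.7% ± 5.81 and 11.1% ± 4.54 (n = 4; exact p = 0.914). Of the 25 shares and ratios tested, 0 passed after adjustment, with a lowest adjusted exact permutation p of 0.476. With a smallest possible p of 0.0286, a class could pass only if most of the 25 tests reached that value together. The adjusted test therefore could hardly call a class and does not show that composition was unchanged.

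Among rarer classes, the mean share of Cd4 cluster 11 was 0.849% ± 0.150 in AG120 and 0.486% ± 0.221 in Vehicle (n = 4; exact p = 0.0571). Cd4 cluster 6 stood at 1.61% ± 0.717 and 1.07% ± 0.227 (n = 4; exact p = 0.171), and NK cells at 2.18% ± 1.28 and 1.38% ± 0.357 (n = 4; exact p = 0.229). Treg cells, which restrain other T cells, stood at 0.255% ± 0.054 and 0.432% ± 0.212 (n = 4; exact p = 0.229). The ratio of CD8 T to Treg cells was 48.1 ± 28 in AG120 and 28.3 ± 9.42 in Vehicle (n = 4; exact p = 0.257). Dendritic cells made up 5.59% ± 1.17 and 5.49% ± 0.818 (n = 4; exact p = 0.914), and endothelial cells 1.77% ± 0.516 and 0.978% ± 0.396 (n = 4; exact p = 0.0857). Macrophage cluster 7 averaged 7.58% of kept cells in AG120 and 0.83% in Vehicle, and cluster 11 averaged 5.23% and 0.8%, neither of them tested. AG120 4 alone held 22.46% and 10.38% in these clusters, whereas AG120 3 held 0.65% and 0.46%.

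By edgeR on cell counts, B cells had a log2 fold change of -0.88 (adjusted p = 0.346), the lowest adjusted p, which 10 other classes shared. In cells with at least 500 genes and at most 5% mitochondrial UMIs, B cells made up 2.49% in AG120 and 2.90% in Vehicle, a difference of -0.41 percentage points against -4.31 among all kept cells. Leaving out each sample in turn, the difference in the CD8 T share ranged from -0.574 (without Vehicle 4) to 3.48 percentage points (without AG120 4), against 0.575 with all samples, and lay below 0 in 5 of the 8 cases. That in the NK share ranged from 0.164 (without AG120 3) to 1.09, against 0.801, and that in the macrophage share from 9.06 (without AG120 4) to 21.4 (without AG120 3), against 13.8. The ranges were -5.10 to -3.43 for B cells, -8.58 to -5.41 for monocytes, -7.78 to -3.72 for neutrophils, -0.252 to -0.095 for Treg cells, 0.318 to 0.873 for Cd4 cluster 6, 0.266 to 0.444 for Cd4 cluster 11, 0.601 to 0.984 for endothelial cells and -0.482 to 0.376 for dendritic cells. The difference in the ratio of CD8 T to Treg cells was 19.8, and ranged from 9.63 without AG120 3 to 32.1 without AG120 4.

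**Figure D2:**
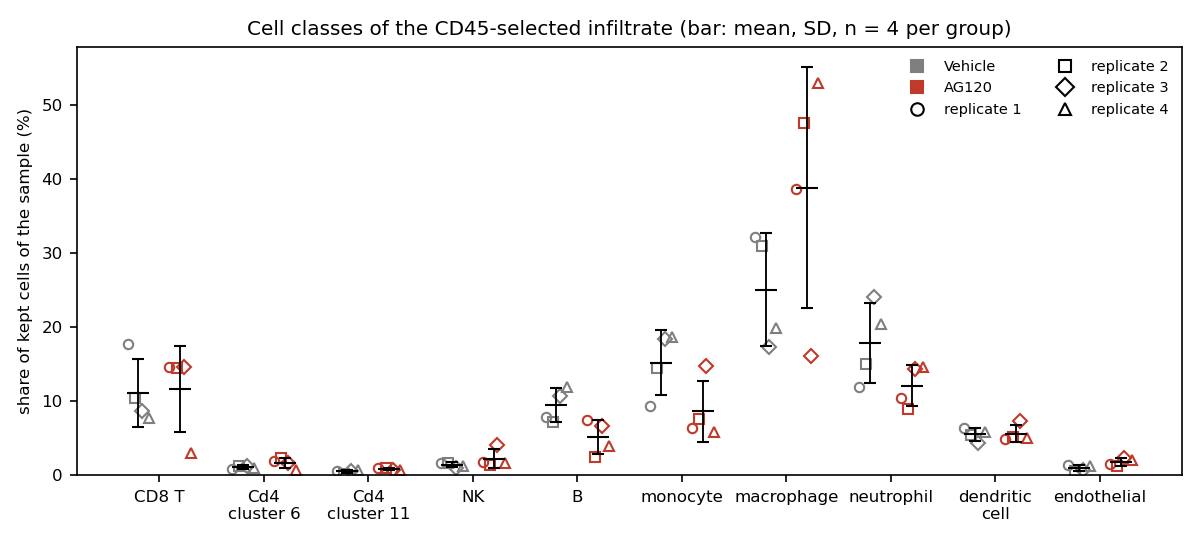
Share of kept cells in each class (%), 1 point per sample, with the mean and SD of 4 samples per group. B cells averaged 5.13% in AG120 and 9.45% in Vehicle, and CD8 T cells 11.7% and 11.1%, with AG120 4 at 2.96%.

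The second comparison asked whether CD8 T cells of treated tumours differ in effector and proliferation transcripts. Granzyme B (Gzmb), which kills target cells, stood at 954 ± 326 CPM in AG120 and 957 ± 211 CPM in Vehicle, with a log2 fold change of 0.00 ± 0.24. Interferon gamma (Ifng) stood at 62.6 ± 23.7 and 82.0 ± 8.88 CPM (-0.45 ± 0.21), perforin (Prf1) at 256 ± 70 and 291 ± 47.6 CPM (-0.18 ± 0.18) and the chemokine Ccl5 at 13932 and 20504 CPM (-0.56 ± 0.30). Leaving out each sample in turn, these ranged from -0.15 to 0.18 (Gzmb), -0.66 to -0.26 (Ifng), -0.39 to -0.08 (Prf1) and -0.71 to -0.33 (Ccl5). In edgeR, 0 of 8911 genes passed the threshold, with 529 at an unadjusted p under 0.05, and DESeq2 called 0. With the replicate number as a block, an alternative given below, edgeR called 114. The simulated test recovered 71.6% of genes changed 2-fold in this comparison. Its genes varied independently, without differences between libraries that many genes share, so recovery in the real samples may be lower.

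Of the gene lists, 4 were called in CD8 T cells. Oxidative phosphorylation genes were higher, 24 of 27 above 0 with a median log2 fold change of 0.20 (adjusted p = 3.94e-06 by camera, adjusted p = 0.864 with an estimated correlation), among them Uqcrc1 (0.49 ± 0.18) and Atp5b (0.30 ± 0.12). Cell cycle genes were higher, 32 of 36 above 0 with a median of 0.30 (adjusted p = 0.000156, adjusted p = 0.927 with an estimated correlation), such as Cdca8 (0.57 ± 0.23) and Ccnb2 (0.61 ± 0.30). The CD8 T cluster led by cycling genes (Top2a, Birc5, Mki67) averaged 2.24% of kept cells in AG120 and 1.54% in Vehicle, untested, with AG120 3 at 4.44%. Mki67, a marker of dividing cells, had a log2 fold change of 0.12 ± 0.21, between -0.15 without AG120 3 and 0.27 without Vehicle 3. Cytoplasmic ribosomal proteins were higher, 18 of 20 above 0 with a median of 0.13 (adjusted p = 0.000767, adjusted p = 0.864 with an estimated correlation). Mitochondrially encoded transcripts were lower, 10 of 12 below 0 with a median of -0.17 (adjusted p = 0.0217, adjusted p = 0.927 with an estimated correlation). In each of these 4 lists 0 members passed over all genes tested and 0 adjusted over the list alone. The cell cycle call was lost without AG120 3 (adjusted p = 0.26), and the mitochondrial call without Vehicle 2 (0.216) or AG120 3 (0.162).

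Other CD8 T cell lists did not pass. Of the cytotoxic effector genes 17 of 23 lay below 0, with a median of -0.15 (adjusted p = 0.174), and of the inhibitory receptor and exhaustion genes 14 of 20, with a median of -0.16 (adjusted p = 0.283). Within the latter, Pdcd1 (0.23 ± 0.15) and Tigit (0.41 ± 0.18) had positive log2 fold changes, and Havcr2 (-0.38 ± 0.17) and Lag3 (-0.11 ± 0.20) negative ones. With 1 sample left out they ranged from 0.11 to 0.36 (Pdcd1), 0.28 to 0.54 (Tigit), -0.49 to -0.24 (Havcr2) and -0.24 to 0.06 (Lag3). Interferon gamma response genes had a median of -0.02 (13 of 24 below 0, adjusted p = 0.774), and turned higher without Vehicle 1 (0.852) or Vehicle 3 (0.951). MHC class I presentation had a median of -0.12 (13 of 18 below 0, adjusted p = 0.0938). Naive and memory genes had a median of 0.04 (6 of 12 above 0, adjusted p = 0.919), with the transcription factor Tcf7 at 0.73 ± 0.52, between 0.45 without AG120 2 and 1.38 without Vehicle 3. Genes of 2-oxoglutarate dependent dioxygenases, the enzymes that the oncometabolite inhibits, had a median of -0.10 (16 of 23 below 0, adjusted p = 0.134), with the DNA demethylase Tet2 at -0.20 ± 0.20, between -0.37 without AG120 1 and -0.04 without Vehicle 1. The cytotoxic list passed, as lower, without Vehicle 1 (adjusted p = 0.0162) or AG120 4 (0.0491), exhaustion genes without Vehicle 3 (0.00665), MHC class I genes without Vehicle 4 (0.0284) and the dioxygenases without AG120 1 (0.0362) or AG120 2 (0.0378). Without AG120 2, edgeR called 1 gene.

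The third comparison asked the same of Cd4 T cells, through Cd4 cluster 6. Targets of NFAT and calcium signalling, which T cell receptor stimulation induces, were lower, with 5 of 6 measured members below 0 and a median log2 fold change of -0.71 (adjusted p = 0.006, adjusted p = 0.815 with an estimated correlation). Nr4a1 (-0.83 ± 0.19), an immediate response gene, and Cd40lg (-1.07 ± 0.29), the ligand by which helper cells activate B cells, were the 2 members lower adjusted over the list alone, and 0 passed over all genes tested. Cd69, an early activation marker, stood at -0.59 ± 0.35, and ranged from -0.84 to -0.22 with 1 sample left out. Dissociation and immediate early genes did not pass there and went both ways, 9 of 15 below 0 with a median of -0.20 (adjusted p = 0.988), with Junb at -0.47 ± 0.14, Fos at -0.94 ± 0.44, Fosb at 0.75 ± 0.37, Hspa8 at 0.44 ± 0.15 and Hsp90ab1 at 0.54 ± 0.16, picked after their values were seen. Inhibitory receptor and exhaustion genes were lower, 9 of 13 below 0 with a median of -0.28 (adjusted p = 0.0474, adjusted p = 0.815 with an estimated correlation). Their 1 member lower adjusted over the list alone was Nr4a1, which both lists hold, and 0 passed over all genes tested. Ctla4 stood at -0.28 ± 0.16, and ranged from -0.32 to -0.15 with 1 sample left out. In edgeR, 0 of 2021 genes passed, with 169 at an unadjusted p under 0.05, and DESeq2 called 4. With the replicate number as a block, edgeR called 42.

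Mitochondrially encoded transcripts in this cluster were lower, 12 of 12 below 0 with a median of -0.34 (adjusted p = 1.5e-06, adjusted p = 0.851 with an estimated correlation), and 3 were lower adjusted over the list alone. Over all passing cells, the median mitochondrial percent was 4.13, 4.05, 3.52 and 3.07 in Vehicle 1 to 4. In AG120 1 to 4 it was 3.77, 3.67, 3.07 and 3.36. Cell quality was not parted from expression in the mitochondrial and ribosomal calls of this or other classes. Ribosomal proteins were higher, 18 of 20 above 0 with a median of 0.16 (adjusted p = 1.39e-05, adjusted p = 0.29 with an estimated correlation), and 5 were higher adjusted over the list alone. This was the 1 list that fry also called (adjusted p = 0.0131). Oxidative phosphorylation genes were higher, 18 of 24 above 0 with a median of 0.26 (adjusted p = 0.0026, adjusted p = 0.862 with an estimated correlation), 0 of them adjusted over the list alone. Glycolysis genes were higher, 9 of 10 above 0 with a median of 0.29 (adjusted p = 0.0283, adjusted p = 0.864 with an estimated correlation). Ldha (0.72 ± 0.19), which makes lactate, was higher and Hk1 (-0.83 ± 0.28) lower adjusted over the list alone. In each of these 4 lists 0 members passed over all genes tested. The residency receptor Cxcr6 stood at -0.57 ± 0.18 (-0.66 to -0.42 with 1 sample left out) and Tcf7 at 0.03 ± 0.33 (-0.09 to 0.30).

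The glycolysis call in Cd4 cluster 6 was lost without Vehicle 2 (adjusted p = 0.137), Vehicle 3 (0.108), AG120 3 (0.146) or AG120 4 (0.0652), and the NFAT call without Vehicle 4 (0.05). The exhaustion call was lost without Vehicle 1 (adjusted p = 0.138), Vehicle 3 (0.0597), Vehicle 4 (0.0924), AG120 3 (0.0941) or AG120 4 (0.128). Without Vehicle 4, edgeR called 4 genes, and without AG120 2 it called 1.

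The fourth comparison concerned NK cells, innate killer lymphocytes. Jun (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222, minus strand, GRCm38), a subunit of the AP-1 transcription factor, rose from 40.7 ± 34 CPM in Vehicle to 188 ± 44.9 CPM in AG120. Its log2 fold change was 2.21 ± 0.38 (edgeR adjusted p = 0.0159), and 4 of 4 AG120 samples lay above every Vehicle sample. In Vehicle 1 to 4 Jun stood at 82.29, 13.91, 11.98 and 54.53 CPM, from NK sums of 86184, 85579, 102140 and 176571 UMIs. The Vehicle level therefore rests on few UMIs. Jun was the only gene of 1617 past the threshold in edgeR, and DESeq2 called 0 (adjusted p of Jun = 0.216). The Jun call was lost without Vehicle 2 (edgeR adjusted p = 0.103), Vehicle 3 (0.0519), AG120 1 (0.0602) or AG120 3 (0.295). Without Vehicle 4 it was also lost (edgeR adjusted p of Jun = 0.0505) while 1 other gene was called. In the stricter cells the edgeR adjusted p of Jun was 0.219. With classes from exact neighbour distances the NK cluster held 940 cells against 665, and Jun was lost with a log2 fold change of 1.03 (edgeR adjusted p = 0.446).

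Dissociation and immediate early genes, to which Jun belongs, were higher in NK cells, 10 of 15 above 0 with a median of 0.21 (adjusted p = 0.00119, adjusted p = 0.851 with an estimated correlation). The 5 members higher adjusted over the list alone were Jun, the only one past the threshold over all genes tested, and the chaperone genes Dnajb1 (1.36 ± 0.30), Hspa8 (0.77 ± 0.18), Hspe1 (0.74 ± 0.23) and Hsp90ab1 (0.46 ± 0.15). Fosb, another AP-1 subunit, stood at -1.31 ± 0.53. Ribosomal proteins were higher, 19 of 20 above 0 with a median of 0.20 (adjusted p = 1.03e-07, adjusted p = 0.815 with an estimated correlation), 2 of them adjusted over the list alone and 0 over all genes tested. Of the cytotoxic genes 12 of 18 lay below 0, with a median of -0.17 (adjusted p = 0.0947). Prf1 stood at -0.26 ± 0.17, Ccl5 at -0.39 ± 0.16 and Gzmb at 0.17 ± 0.33, the last between -0.18 without AG120 4 and 0.41 without Vehicle 4. The cytotoxic list passed, as lower, without Vehicle 1 (adjusted p = 0.0111), AG120 3 (0.0481) or AG120 4 (0.00931).

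The fifth comparison concerned B cells. Pde3b (ENSMUSG00000030671, chromosome 7, 114415281 to 114539251, plus strand, GRCm38), a phosphodiesterase that degrades cyclic AMP, rose from 27.9 ± 3.87 CPM in Vehicle to 67.5 ± 8.54 CPM in AG120. Its log2 fold change was 1.22 ± 0.21 (edgeR adjusted p = 0.0399), and 4 of 4 AG120 samples lay above every Vehicle sample. NFAT and calcium signalling targets were lower, 8 of 8 below 0 with a median of -0.48 (adjusted p = 5.64e-05, adjusted p = 0.29 with an estimated correlation). Of these, Egr1 (-0.78 ± 0.21), Nr4a1 (-0.47 ± 0.15), Cd69 (-0.56 ± 0.20), Egr3 (-0.61 ± 0.24) and Irf4 (-0.49 ± 0.20), genes that B cell receptor stimulation induces and, for Egr1 and Nr4a1, also cell stress, were lower adjusted over the list alone, and 0 passed over all genes tested. The dissociation and immediate early list did not pass, 11 of 19 above 0 with a median of 0.07 (adjusted p = 0.914). Among its members, picked after their values were seen, Atf3 stood at -0.94 ± 0.28, Fosb at -0.50 ± 0.21 and Junb at -0.40 ± 0.17, and the chaperone gene Hspa8 at 0.67 ± 0.15.

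Oxidative phosphorylation genes were higher in B cells, 23 of 27 above 0 with a median of 0.30 (adjusted p = 6.69e-07, adjusted p = 0.815 with an estimated correlation), and so were cell cycle genes, 17 of 21 with a median of 0.30 (adjusted p = 0.007, adjusted p = 0.936 with an estimated correlation). Mitochondrially encoded transcripts were lower, 12 of 12 below 0 with a median of -0.25 (adjusted p = 2.5e-05, adjusted p = 0.851 with an estimated correlation), 4 of them adjusted over the list alone. B cell transcripts were lower, 10 of 12 below 0 with a median of -0.13 (adjusted p = 0.0166, adjusted p = 0.815 with an estimated correlation), including Ighd (-0.48 ± 0.16) and Ighm (-0.40 ± 0.15), heavy chains of the B cell receptor. In these 4 lists 0 members passed over all genes tested, and outside the mitochondrial list 0 passed adjusted over the list alone. MHC class II presentation had a median of 0.06 (10 of 11 above 0, adjusted p = 0.174), and passed, as higher, without Vehicle 1 (adjusted p = 0.0235), with H2-Ab1 at 0.04 ± 0.12 (-0.03 to 0.13 with 1 sample left out).

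Pde3b was the only gene of 5473 past the threshold in edgeR, and DESeq2 called 0 (adjusted p of Pde3b = 0.0995). The Pde3b call was kept without AG120 2, where 3 genes were called, and was lost without Vehicle 1 (edgeR adjusted p = 0.223), Vehicle 2 (0.138), Vehicle 3 (0.229), Vehicle 4 (0.0505), AG120 1 (0.0556), AG120 3 (0.112) or AG120 4 (0.0825). In the stricter cells the log2 fold change of Pde3b was 0.73 (edgeR adjusted p = 0.998), and with sums thinned to the smallest sample it was 1.82 (edgeR adjusted p = 0.0935). The cell cycle call was lost without Vehicle 1 (adjusted p = 0.332), Vehicle 4 (0.0598) or AG120 1 (0.224).

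**Figure D3:**
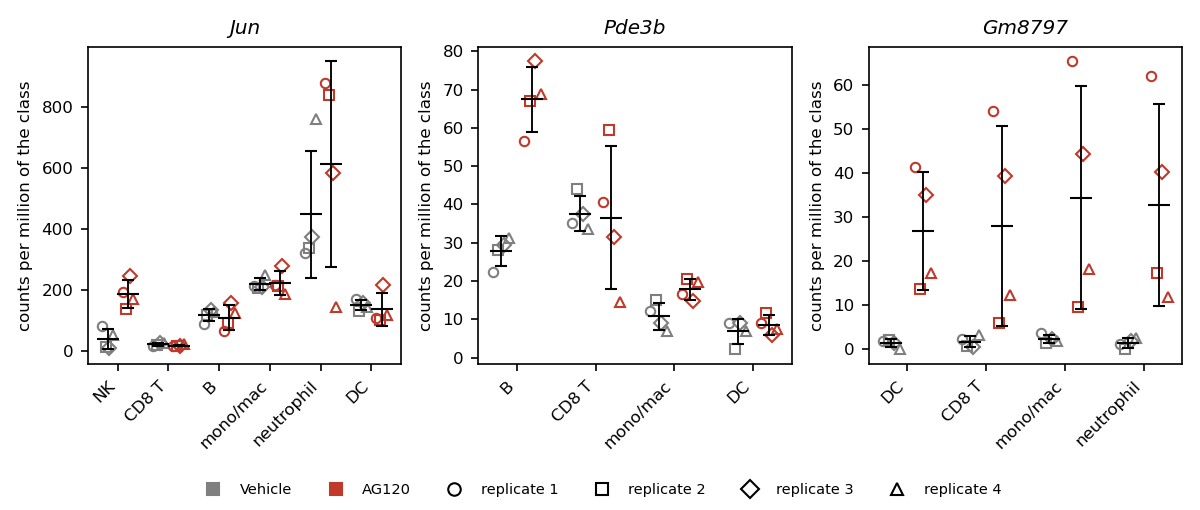
CPM of Jun, Pde3b and Gm8797, the genes past the edgeR threshold, in each class where they were tested, 1 point per sample with the mean and SD of 4 samples per group. Jun averaged 188 CPM in NK cells of AG120 and 40.7 CPM in those of Vehicle, and Pde3b 67.5 and 27.9 CPM in B cells.

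The sixth comparison concerned monocytes and macrophages, the largest part of the infiltrate. Macrophage transcripts were higher in AG120, 12 of 12 above 0 with a median log2 fold change of 0.61 (adjusted p = 2.5e-05, adjusted p = 0.815 with an estimated correlation), including the complement gene C1qa (0.84 ± 0.34) and the lipid carrier Apoe (1.30 ± 0.46). Cell cycle genes were higher, 35 of 36 above 0 with a median of 0.73 (adjusted p = 5.64e-05, adjusted p = 0.936 with an estimated correlation), such as Bub1 (1.13 ± 0.40) and Tyms (1.20 ± 0.48), and Mki67 stood at 0.73 ± 0.44, between 0.19 without AG120 4 and 0.99. Macrophage cluster 17, led by cycling genes, averaged 2.59% of kept cells in AG120 and 1.05% in Vehicle, untested, with 6.77% in AG120 4 and at most 2.01% in any other sample. Neutrophil transcripts were lower, 10 of 12 below 0 with a median of -0.68 (adjusted p = 0.000204, adjusted p = 0.851 with an estimated correlation), 1 of them, Lcn2 (-1.46 ± 0.37), adjusted over the list alone. Macrophage clusters 7 and 11, which AG120 4 filled most, lay within this class and averaged 7.58% and 5.23% of kept cells in AG120 against 0.83% and 0.8% in Vehicle. Macrophages made up more of the class in AG120 by mean share, as given above.

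Hypoxia response genes were higher in monocytes and macrophages, 16 of 18 above 0 with a median of 0.26 (adjusted p = 0.00309, adjusted p = 0.864 with an estimated correlation). The stress gene Ddit4 (0.64 ± 0.14) was the 1 member higher adjusted over the list alone, and Vegfa, the vascular growth factor, stood at -0.11 ± 0.30 (-0.34 to 0.09 with 1 sample left out). Glycolysis genes were higher, 11 of 15 above 0 with a median of 0.19 (adjusted p = 0.0236, adjusted p = 0.864 with an estimated correlation). Dissociation and immediate early genes were higher, 13 of 21 above 0 with a median of 0.16 (adjusted p = 0.00309, adjusted p = 0.815 with an estimated correlation). Their 5 members higher adjusted over the list alone were chaperone genes, Hsph1 (1.12 ± 0.22), Hspa1a (1.15 ± 0.26), Dnajb1 (0.47 ± 0.13), Dnaja1 (0.45 ± 0.12) and Hspa8 (0.59 ± 0.18). Genes of alternative or suppressive macrophages were higher, 14 of 20 above 0 with a median of 0.35 (adjusted p = 0.0347, adjusted p = 0.864 with an estimated correlation), with Arg1, which depletes arginine, at 0.52 ± 0.31 (0.28 to 0.73 with 1 sample left out) and Spp1 at 0.75 ± 0.47 (0.50 to 1.04). The Treg suppressive programme was higher, 11 of 12 above 0 with a median of 0.40 (adjusted p = 0.0295, adjusted p = 0.815 with an estimated correlation). Its leading members here were Areg (0.85 ± 0.24), a growth factor, and Il10 (0.61 ± 0.35), a cytokine that macrophages also make. In all 8 lists of this class 0 members passed over all genes tested, and in the 5 lists for which no count is given here 0 passed adjusted over the list alone.

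Interferon gamma response genes did not pass, 25 of 31 below 0 with a median of -0.15 (adjusted p = 0.145). Cd274 stood at -0.28 ± 0.31 and Cxcl9, a chemokine that draws T cells, at -0.24 ± 0.59. With 1 sample left out, Cd274 ranged from -0.51 without AG120 2 to -0.02 without AG120 4, and Cxcl9 from -0.56 without Vehicle 3 to 0.64 without Vehicle 1. MHC class II presentation had a median of 0.22 (8 of 11 above 0, adjusted p = 0.112) and T cell attracting chemokines a median of 0.38 (5 of 9 above 0, adjusted p = 0.414). Il1b stood at -0.25 ± 0.18 (-0.36 to -0.09, the latter without AG120 4), Idh1 at 0.92 ± 0.43 (0.29 to 1.15, the former without AG120 4, which held 362 CPM against 86 to 152 CPM in the other AG120 samples) and Tet2 at -0.47 ± 0.17, the last with 4 of 4 AG120 samples below every Vehicle sample and an edgeR adjusted p of 0.632. In edgeR, 0 of 10559 genes passed, with 823 at an unadjusted p under 0.05, and DESeq2 called 19. Without clusters 7 and 11, edgeR also called 0.

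Without macrophage clusters 7 and 11, chosen after seeing the data, the calls of alternative or suppressive macrophage genes (adjusted p = 0.114) and of the Treg suppressive programme (0.0925) were lost, and Mki67 stood at 1.21. In macrophages alone these calls (adjusted p = 0.17 and 0.181), the dissociation and immediate early call (0.166) and the neutrophil transcript call (0.463) were lost. The glycolysis and hypoxia response tests pointed lower there without passing. Their medians were 0.01 (8 of 15 above 0) and -0.07 (6 of 18 above 0). Arg1 stood at 0.00 and Spp1 at 0.25 in macrophages alone. In monocytes alone the alternative macrophage call (adjusted p = 0.149) and the glycolysis call (0.108) were lost and cell cycle genes turned lower (0.0562). Arg1 stood at 1.24 and Tet2 at -0.13 in monocytes. Only 11 cell cycle genes and 13 alternative macrophage genes were measured there, against 36 and 20 in macrophages alone.

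The mono/mac cell cycle call was lost without AG120 4 (adjusted p = 0.359), and the hypoxia call without Vehicle 4 (0.0512) or AG120 2 (0.171). Glycolysis was lost without Vehicle 3 (adjusted p = 0.0542), AG120 1 (0.136) or AG120 2 (0.342), and alternative macrophage genes without Vehicle 3 (0.097), Vehicle 4 (0.079), AG120 1 (0.149) or AG120 2 (0.22). The Treg programme was lost without Vehicle 1 (adjusted p = 0.0902), Vehicle 4 (0.132), AG120 1 (0.163), AG120 2 (0.0869) or AG120 3 (0.0615). Interferon gamma response genes passed, as lower, without Vehicle 2 (adjusted p = 0.00194), Vehicle 3 (0.00124), AG120 2 (0.021) or AG120 3 (0.0272), and turned higher without Vehicle 1 (0.961) or AG120 4 (0.49). Without Vehicle 1, MHC class II presentation (adjusted p = 0.000121) and T cell attracting chemokines (0.0302) passed as higher. Clusters 7 and 11 stayed in the class in each of these fits.

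The seventh comparison concerned neutrophils. Their own transcripts were lower, 14 of 14 below 0 with a median log2 fold change of -0.54 (adjusted p = 1.27e-06, adjusted p = 0.815 with an estimated correlation), including Mmp9 (-0.56 ± 0.18) and Ltf (-1.14 ± 0.45), which encode granule proteins. Neutrophil cluster 15, led by the granule genes Ngp, Camp, Ltf and Lcn2, averaged 1.12% of kept cells in AG120 and 3.47% in Vehicle, untested, and lay within this class. Type I interferon response genes were higher, 22 of 23 above 0 with a median of 0.43 (adjusted p = 1.34e-05, adjusted p = 0.864 with an estimated correlation), such as the antiviral genes Rtp4 (0.76 ± 0.27) and Ifit3b (1.67 ± 0.68), and Isg15 stood at 0.57 ± 0.36, between 0.33 and 0.85 with 1 sample left out. Ribosomal proteins were higher, 20 of 20 above 0 with a median of 0.42 (adjusted p = 2.47e-07, adjusted p = 0.864 with an estimated correlation). MHC class II presentation was higher, 7 of 7 above 0 with a median of 0.85 (adjusted p = 0.001, adjusted p = 0.864 with an estimated correlation), with H2-Ab1 at 0.42 ± 0.63, and between 0.04 without Vehicle 3 and 1.16 without Vehicle 1. Transcripts of other cell types moved with them: macrophage transcripts were higher, 8 of 10 above 0 with a median of 0.48 (adjusted p = 0.0363, adjusted p = 0.862 with an estimated correlation), led by C1qa (1.88 ± 0.57).

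Cytotoxic effector genes were higher in neutrophils, 9 of 9 above 0 with a median of 0.65 (adjusted p = 0.006, adjusted p = 0.851 with an estimated correlation). The 1 member higher adjusted over the list alone was Tnf (0.98 ± 0.28), an inflammatory cytokine, and Gzma, a killer cell gene, stood at 22.2 ± 17.2 CPM against 4.98 ± 4.45 CPM. Inflammatory cytokines and NF-kB targets were higher, 16 of 22 above 0 with a median of 0.23 (adjusted p = 0.0143, adjusted p = 0.894 with an estimated correlation), and Il1b stood at -0.06 ± 0.19 (-0.16 to 0.00 with 1 sample left out). In these 7 lists 0 members passed over all genes tested, and Tnf in the cytotoxic list was the 1 member past the threshold adjusted over the list alone. In edgeR, 0 of 6084 genes passed, with 508 at an unadjusted p under 0.05, and DESeq2 called 6. The cytotoxic call was lost without Vehicle 4 (adjusted p = 0.0547) or AG120 2 (0.0702), and the NF-kB call without Vehicle 3 (0.0973), AG120 1 (0.352) or AG120 2 (0.109). The macrophage transcript call was lost without Vehicle 3 (adjusted p = 0.189), Vehicle 4 (0.0987), AG120 1 (0.149), AG120 3 (0.0724) or AG120 4 (0.0742), and without AG120 4 edgeR called 2 genes.

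The eighth comparison concerned dendritic cells, which present antigen to T cells. Interferon gamma response genes were lower, 23 of 29 below 0 with a median log2 fold change of -0.25 (adjusted p = 0.00779, adjusted p = 0.894 with an estimated correlation), among them Wars (-0.56 ± 0.21), Gbp3 (-0.60 ± 0.25) and the inhibitory ligand Cd274 (-0.51 ± 0.23). Cell cycle genes were higher, 21 of 32 above 0 with a median of 0.17 (adjusted p = 0.00517, adjusted p = 0.936 with an estimated correlation), led by the replication genes Mcm2 (0.80 ± 0.24) and Mcm6 (0.62 ± 0.20). Ribosomal proteins were higher, 19 of 20 above 0 with a median of 0.18 (adjusted p = 1.36e-06, adjusted p = 0.864 with an estimated correlation), and mitochondrially encoded transcripts lower, 10 of 12 below 0 with a median of -0.17 (adjusted p = 0.0188, adjusted p = 0.936 with an estimated correlation). T cell transcripts were higher beside them, 8 of 8 above 0 with a median of 0.63 (adjusted p = 0.00404, adjusted p = 0.864 with an estimated correlation).

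Dissociation and immediate early genes were higher in dendritic cells, 13 of 21 above 0 with a median of 0.06 (adjusted p = 0.007, adjusted p = 0.862 with an estimated correlation). Of these 6 were higher adjusted over the list alone, including the chaperones Hsph1 (1.24 ± 0.24) and Hspa8 (0.58 ± 0.15), and Junb (-0.37 ± 0.12), an AP-1 subunit, was lower. In the 6 lists 0 members passed over all genes tested, and in the other 5 lists 0 passed adjusted over the list alone. Tet2 stood at -0.52 ± 0.22 and Vegfa at -0.89 ± 0.54, the latter between -1.28 and -0.58 with 1 sample left out. The only gene of 7857 past the edgeR threshold was Gm8797 (ENSMUSG00000103034, chromosome 3, 5750806 to 5751295, plus strand, GRCm38), named after its values were seen. It stood at 26.9 ± 13.4 CPM in AG120 and 1.39 ± 0.97 CPM in Vehicle, a log2 fold change of 4.60 ± 0.59 (edgeR adjusted p = 0.0216), with 4 of 4 AG120 samples above every Vehicle sample. Its transcript shares 384 bases at 98.2% identity with Ubb, a ubiquitin gene, so its counts are uncertain. DESeq2 also called 1 gene.

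The log2 fold change of Gm8797 was 3.90 in CD8 T cells (edgeR adjusted p = 0.767), 3.92 in monocytes and macrophages (0.361), 4.19 in neutrophils (0.127) and 3.46 over all cells (0.435). The Gm8797 call in dendritic cells was lost without Vehicle 1 (edgeR adjusted p = 0.0874), Vehicle 2 (0.134) or Vehicle 3 (0.196), and with classes from resolution 2 (0.0808) or from exact neighbour distances (0.102). The cell cycle call was lost without Vehicle 1 (adjusted p = 0.0675), Vehicle 2 (0.579) or AG120 4 (0.616), and the dissociation call without Vehicle 4 (0.0705) or AG120 3 (0.211). Interferon gamma response was lost without Vehicle 1 (adjusted p = 0.21), Vehicle 4 (0.396) or AG120 3 (0.201), and T cell transcripts without Vehicle 4 (0.287) or AG120 1 (0.119). The mitochondrial call was lost without Vehicle 1 (adjusted p = 0.1), Vehicle 2 (0.215), AG120 3 (0.15) or AG120 4 (0.236), and with classes from exact distances (0.085).

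The last comparison summed all kept cells, where composition and expression within cells add up. Neutrophil transcripts were lower, 14 of 14 below 0 with a median log2 fold change of -1.27 (adjusted p = 1.47e-09, adjusted p = 0.851 with an estimated correlation), and B cell transcripts lower, 11 of 12 below 0 with a median of -0.96 (adjusted p = 2.84e-07, adjusted p = 0.851 with an estimated correlation). Adjusted over the list alone, 3 neutrophil transcripts, including Il1f9 (-1.26 ± 0.31), and 6 B cell transcripts, including Pax5 (-1.08 ± 0.34), were lower. Macrophage transcripts were higher, 12 of 12 above 0 with a median of 0.78 (adjusted p = 0.000767, adjusted p = 0.864 with an estimated correlation). Genes of 2-oxoglutarate dependent dioxygenases were lower, 19 of 23 below 0 with a median of -0.15 (adjusted p = 0.00517, adjusted p = 0.864 with an estimated correlation). Their 2 members lower adjusted over the list alone were Tet2 (35 ± 4.62 CPM against 49.0 ± 4.24 CPM, -0.48 ± 0.12, 4 of 4 AG120 samples below every Vehicle sample) and the histone demethylase Kdm7a (-0.46 ± 0.12). The list did not pass in monocytes alone (median 0.03, camera adjusted p = 0.526) or macrophages alone (-0.10, 0.301), adjusted over their 50 list tests. Tet2 stood at 72.7 CPM in AG120 and 79.0 CPM in Vehicle in monocytes, and at 34.3 and 42.3 CPM in macrophages. Tet2 was also lower in dendritic cells, as given above. The sum does not part composition from expression.

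Over all cells, cell cycle genes were higher, 34 of 36 above 0 with a median of 0.23 (adjusted p = 5.07e-05, adjusted p = 0.891 with an estimated correlation), and ribosomal proteins higher, 18 of 20 with a median of 0.12 (adjusted p = 0.0026, adjusted p = 0.864 with an estimated correlation). Naive and memory T cell genes were lower, 10 of 15 below 0 with a median of -0.39 (adjusted p = 0.00616, adjusted p = 0.864 with an estimated correlation). Alternative macrophage genes were higher, 14 of 20 above 0 with a median of 0.38 (adjusted p = 0.0352, adjusted p = 0.891 with an estimated correlation). Oxidative phosphorylation genes were higher, 23 of 27 above 0 with a median of 0.09 (adjusted p = 0.0362, adjusted p = 0.936 with an estimated correlation). Hepatocyte transcripts were higher, 11 of 14 above 0 with a median of 0.55 (adjusted p = 0.0382, adjusted p = 0.864 with an estimated correlation), led by Fabp1 (1.46 ± 0.51). In the 10 lists called over all cells 0 members passed over all genes tested, and in the 7 lists for which no count is given here 0 passed adjusted over the list alone. Il1b stood at -0.43 ± 0.12, with 4 of 4 AG120 samples below every Vehicle sample, and Idh1 at 114 ± 116 CPM against 50.4 ± 16.2 CPM, a log2 fold change of 1.18, between 0.17 without AG120 4 and 1.48 without AG120 3.

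Other lists did not pass over all cells. The interferon gamma response had a median of -0.13 (23 of 33 below 0, adjusted p = 0.25) and stromal and endothelial transcripts a median of 0.15 (9 of 14 above 0, adjusted p = 0.371). T cell transcripts had a median of 0.16 and 11 of 12 above 0, while the test pointed lower (adjusted p = 0.919). Without AG120 4, T cell transcripts passed as higher (adjusted p = 3.69e-07). Epithelial or tumour transcripts had a median of 0.03 and a mean of -0.07 (adjusted p = 0.767, lower), erythrocyte transcripts a median of -0.26 with the test pointing higher (adjusted p = 0.461), and TGF-beta response genes a median of 0.05 with the test pointing lower (adjusted p = 0.767). Genes of the tricarboxylic acid cycle and 2-oxoglutarate metabolism had a median of 0.00 (13 of 25 above 0, adjusted p = 0.919). In edgeR, 0 of 13459 genes passed, with 1072 at an unadjusted p under 0.05, and DESeq2 called 48.

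Over all cells, the macrophage call was lost without AG120 4 (adjusted p = 0.105), as were the calls of 2-oxoglutarate dependent dioxygenases (0.0654) and of naive and memory genes (0.342). Alternative macrophage genes were lost without Vehicle 3 (adjusted p = 0.138), Vehicle 4 (0.0699), AG120 1 (0.102), AG120 2 (0.29) or AG120 4 (0.123). Hepatocyte transcripts were lost without Vehicle 1 (adjusted p = 0.204), Vehicle 3 (0.0666), AG120 1 (0.0695), AG120 3 (0.241) or AG120 4 (0.111), and oxidative phosphorylation without Vehicle 1 (0.0716), Vehicle 2 (0.091), Vehicle 3 (0.0975) or AG120 4 (0.938). The interferon gamma response passed, as lower, without Vehicle 2 (adjusted p = 0.00832) or Vehicle 3 (0.00427), and turned higher without Vehicle 4 (0.906).

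**Figure D4:**
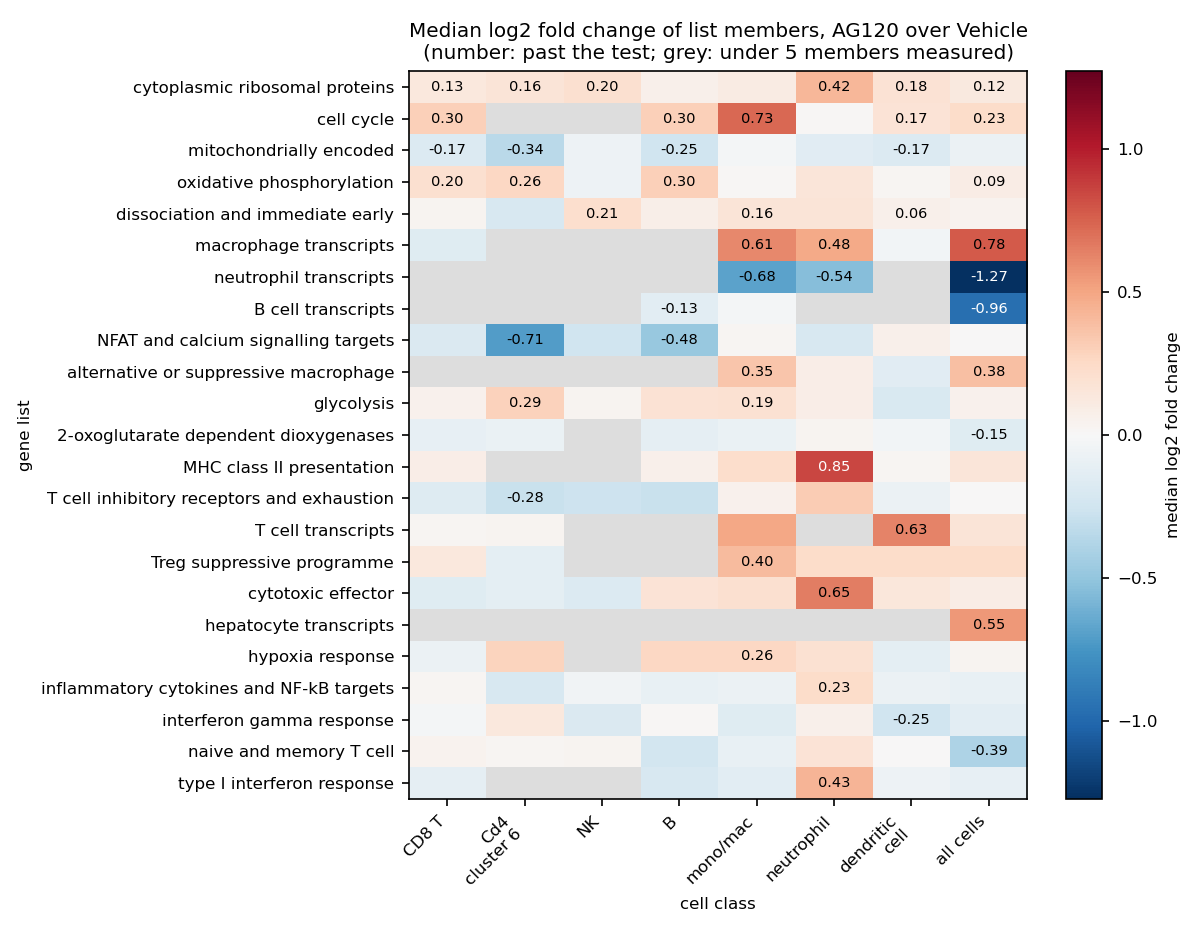
Median log2 fold change (AG120 over Vehicle, colour) of the members of each gene list called in at least 1 class, with the value printed where camera with the preset correlation called the list. Neutrophil transcripts had the lowest printed median, -1.27 over all cells, and MHC class II presentation in neutrophils the highest, 0.85; with an estimated correlation 0 lists were called.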

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

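The tests for RNA from other libraries, for cells of both sexes and for AG120 treatment alone, and the comparison of Jun, Pde3b and Gm8797 between classes, were chosen after the result was seen. Dixon's rule for a sample apart from 3 others marks about 1 in 20 groups by chance, and it marked a sample in 14 of 140 groups tested.

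In the AG120 group, AG120 4 stood apart with 2.96% CD8 T cells (others 14.5% to 14.7%), 4.84% T cells (17.9% to 18.5%) and CD8 T cells as 61.1% of T cells (79.0% to 81.4%). AG120 3 stood apart with 4.09% NK cells (1.32% to 1.71%), 2.64% pDC (0.403% to 0.686%) and 7.33% dendritic cells (4.84% to 5.12%). In CD8 T cells, Prf1 stood at 359.79 CPM in AG120 2 (208 to 232), Tcf7 at 24.2 CPM in Vehicle 3 (6.13 to 7.49), Mki67 at 224 CPM in AG120 3 (121 to 136) and Tet2 at 28.6 CPM in AG120 1 (19.6 to 21). Over all cells, Idh1 stood at 285.6 CPM in AG120 4 (35.6 to 76.4).

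The effect on Jun in NK cells differed from its mean effect in 5 other classes by 2.66 on the log2 scale (exact permutation p = 0.0286), and that on Pde3b in B cells from its mean in 3 other classes by 0.95 (exact permutation p = 0.0286). Both genes were picked by their effect in the named class, so these p-values are too low. The same comparison for Gm8797 gave 0.24 (exact permutation p = 0.771).

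Xist at 1.3 CPM (other Vehicle samples 229 to 255) and Y-linked genes at 126.48 CPM (0.07 to 7.01) set Vehicle 1 apart, and Y-linked genes at 94.27 CPM (0.3 to 4.19) set AG120 2 apart. If RNA from other libraries had caused the mixture in AG120 2, cells with both kinds of UMI would be about as frequent as independent draws give, but 10 were found against 100.6 expected, a ratio of 0.099 (0.048 to 0.183). Cells of both sexes in 1 library remain the likely reading, since 13.63% of deep cells held only Xist. Values in monocytes and macrophages argued against cells of the Vehicle 1 suspension: Y-linked cells there lay 0.069 (-0.014 to 0.151) further toward Vehicle 1 than Xist cells, where 1 is the whole way. The shift was 0.205 (0.077 to 0.327) in dendritic cells, -0.02 (-0.158 to 0.13) in CD8 T cells and -0.84 (-1.253 to -0.516) in neutrophils, the last from 10 and 36 cells. Gm8797, left out of that comparison, went the other way. Y-linked cells of AG120 2 held 5.97 CPM (3.93 to 8.68), near the 4.3 CPM (3.25 to 5.58) of Vehicle 1. Xist cells of AG120 2 held 35.06 CPM (26.26 to 45.86), so cells of the Vehicle 1 suspension are not excluded. No biological explanation was tested, because the labels give no sex.

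Exchanging Vehicle 1 and AG120 3 between the groups gave 522 genes in monocytes and macrophages, where the labelled groups gave 0. Exchanged labels remain possible but were not tested independently. Of 290 genes called from the other 6 libraries, 62.8% put both libraries on the other group's side and 3.1% on their own. The split was picked because it called the most genes in this class. The share of 62.8%, from the same counts, largely repeats that choice and is no support for exchanged labels. The criterion written before the test was met by that share, but it was changed afterwards to need 2 classes with 20 such genes, and only this class, where the split was noticed, had them, so the label became undecided. Other macrophage clusters in both libraries could also account for it in part, as 258 genes stayed without clusters 7 and 11. The exchange gave 2 genes in macrophages alone and 66 in monocytes alone, against 0 and 2 as labelled, so the balance of both cell types may also contribute. That split also puts Vehicle 1 and AG120 2, the libraries with many Y-linked UMIs, on 1 side, and Gm8797 follows the labels, not the exchange.

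Gm8797 was higher in all 4 AG120 samples. AG120 treatment alone stayed open. Xist cells of AG120 2 held 5.88 times (3.63 to 9.71) the level of Y-linked cells of the same library, and those of AG120 3 held 2.47 times (1.13 to 6.76), but these intervals cover counting error only. Xist cells of AG120 1, 3 and 4 differed 3.2 times between libraries, and the criterion was changed after the values were seen to ask for more than that in both libraries. Reads shared with paralogs could not be judged: of 3 genes with similar transcripts only Ubb had values, a log2 fold change of 0.26, and the gain of Gm8797 equals 2.83% of the 971.1 CPM of Ubb. A substrain marked by Nnt could not be judged either: the gap of 0.46 met the criterion against it, but Nnt lay at 0.24 to 0.61 CPM in every library and the label was changed to undecided for that reason. Sex alone is argued against by Xist cells, where Gm8797 stood at 1.98, 2.18 and 2.31 CPM in Vehicle 2, 3 and 4. In Xist cells of AG120 1, 3 and 4 it stood at 52.05, 37.38 and 16.25 CPM. The highest upper bound of these Vehicle samples was 3.46 CPM and the lowest lower bound of these AG120 samples 14.47 CPM. Differences in origin or genotype between the animals stay open.

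Grouping the 8 samples in each of the 35 possible ways tests whether the labelled grouping gives more calls than others. Where 0 genes were called by label, 35 of 35 splits count as at least as large by construction, which says nothing about chance: other splits gave at most 8 genes in CD8 T cells, 2 in Cd4 cluster 6, 522 in monocytes and macrophages, 4 in neutrophils and 25 over all cells. Counts of genes at least as large arose in 4 splits for NK cells (1 by label, at most 6 otherwise), 8 for B cells (1, 8), 7 for dendritic cells (1, 29) and 8 over all classes (3, 551). Counts of lists at least as large arose in 32 splits for CD8 T cells (4, 8), 18 for NK cells (2, 5), 15 for B cells (5, 8) and 22 for monocytes and macrophages (8, 18). They arose in 26 for neutrophils (7, 14), 26 for dendritic cells (6, 12), 26 for all cells (10, 16) and 20 over all classes (48, 64). Only for lists in Cd4 cluster 6 was the labelled grouping the highest, 1 of 35 (6, 5), and with 18 counts examined 1 such result is not rare. The split with 522 genes, where the labelled grouping gave 0, is the exchange weighed above, and it points to a structure of the samples that the labels do not give; whether that is treatment under exchanged labels stays open.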

How the results depend on the processing

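The alternatives with exact neighbour distances, with 6 libraries and with monocytes or macrophages alone were chosen after the result was seen. The cause was not tested for any value below unless a setting's smaller number of samples or cells gives it.

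Of the alternatives, 391 values of shares, 674 of named genes and 874 of lists kept their direction and side of the threshold. Shares tested by permutation could hardly pass the threshold at all, so for them only the direction is informative. Among named genes only Jun, Pde3b and Gm8797 had a call to lose, and all lost calls of named genes are theirs. For the other named genes, staying short of the threshold says little. Calls were lost in 201 values of lists and 24 of named genes, gained in 29 and 1, and direction turned in 26, 25 and, for shares, 20. Counts of genes kept within 1.5 times in 80 of 136 values and counts of lists in 117 of 137. Most comparisons had 0 genes called to begin with, and 0 against 0 counts as kept, so the gene counts say little about stability. A kept count can also come from another gene, as in NK cells without Vehicle 4.

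Genes called by DESeq2 numbered 4 in Cd4 cluster 6, 0 in NK cells, 0 in B cells, 19 in monocytes and macrophages, 6 in neutrophils and 48 over all cells. Without a filter on low counts they numbered 25 in Cd4 cluster 6, 14 in NK cells, 24 in B cells, 87 in neutrophils and 30 in dendritic cells. From 6 libraries they numbered 4 in CD8 T cells, 1 in Cd4 cluster 6, 2 in NK cells, 4 in B cells, 1 in monocytes and macrophages, 8 in neutrophils, 5 in dendritic cells and 2 over all cells. Stricter cells and thinned sums each gave 0 in NK and 0 in B cells, resolution 2 gave 2 in NK and 0 in dendritic cells, and monocytes alone gave 2. Classes from exact neighbour distances, where 95.2% of cells kept their class (adjusted Rand index of clusters 0.799), gave 0 in NK and 0 in dendritic cells, and there Jun had a log2 fold change of 1.03 (edgeR adjusted p = 0.446) and Gm8797 one of 4.68 (0.102). Called lists numbered 0 in all 8 comparisons with an estimated correlation and with fry, except 1 in Cd4 cluster 6 with fry. They numbered 5 over all cells in stricter cells and 4 in macrophages alone.

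Whether the replicate numbers pair the samples stays unknown. Deviations of same-numbered samples from their group means had correlations of 0.098, 0.025, 0.285 and 0.112, all positive. Other pairs had correlations of -0.271 to 0.318, the highest between Vehicle 1 and AG120 2, the libraries with many Y-linked UMIs. With the replicate number as a block, edgeR called 114 genes in CD8 T cells, 42 in Cd4 cluster 6, 6 in NK cells, 3 in B cells, 1 in monocytes and macrophages and 12 in dendritic cells, and Cxcl9 in monocytes and macrophages turned to 0.16.

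Shares turned under the centred log ratio for CD8 T cells (-0.213), cDC (-0.074), pDC (-0.376) and mast cells or basophils (-0.039), and in stricter cells for fibroblasts (-0.039). Log2 fold changes turned for Gzmb in CD8 T cells (0.01 with RLE factors, 0.01 without the filter), Il1b in neutrophils (0.06 in stricter cells), H2-Ab1 in B cells (-0.03 thinned, -0.11 in stricter cells) and Cxcl9 (0.54 from 6 libraries). In monocytes alone Cxcl9 (1.27) and Il1b (0.06) turned. Lists turned, by adjusted p, in stricter cells for MHC class II in B cells (0.92) and T cell transcripts over all cells (0.92), and from 6 libraries for naive and memory genes in CD8 T cells (0.653), epithelial transcripts (0.933) and T cell transcripts over all cells (0.984). In macrophages alone glycolysis (0.907), hypoxia (0.786) and MHC class II (0.907) turned. In monocytes alone cell cycle (0.0562, from 11 measured genes) and interferon gamma response (0.000498) turned. Each was adjusted together with the lists of the other comparisons.

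Leaving out 1 sample, called genes ranged from 0 to 3 in B cells, 0 to 1 in CD8 T cells, 0 to 4 in Cd4 cluster 6, and 0 to 2 in NK cells, dendritic cells and neutrophils, and called lists from 3 to 7 in dendritic cells and 5 to 11 in monocytes and macrophages. Share differences ranged from -0.574 to 3.48 (CD8 T), 0.164 to 1.09 (NK), -0.36 to 0.413 (cDC), -0.482 to 0.376 (dendritic), -0.069 to 0.116 (mast), -0.122 to 0.036 (mature DC), -0.427 to 0.317 (pDC) and -0.112 to 0.962 (plasma). Log2 fold changes ranged from -0.15 to 0.18 (Gzmb, CD8 T), -0.18 to 0.41 (Gzmb, NK), -0.24 to 0.06 (Lag3, CD8 T), -0.15 to 0.27 (Mki67, CD8 T), -0.09 to 0.30 (Tcf7, Cd4 cluster 6) and -0.03 to 0.13 (H2-Ab1, B). In monocytes and macrophages they ranged from -0.56 to 0.64 (Cxcl9) and -0.34 to 0.09 (Vegfa). For these lists, all of which turned direction without at least 1 sample, adjusted p ranged from 3.69e-07 to 0.918 (T cell), 0.503 to 0.947 (TGF-beta), 0.189 to 0.946 (epithelial), 0.00427 to 0.977 (interferon gamma) and 0.25 to 0.989 (tricarboxylic acid cycle) over all cells. In CD8 T cells it ranged from 0.242 to 0.995 (interferon gamma) and 0.241 to 0.977 (naive and memory), and in monocytes and macrophages from 0.00124 to 0.961 (interferon gamma).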

Other observations

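The tests of monocytes and macrophages apart were chosen after the result was seen, as were the genes of the last paragraph. List p values here were adjusted over the 50 list tests of these cell types. In monocytes alone, MHC class II presentation was higher in AG120, 8 of 8 above 0 with a median log2 fold change of 0.68, 6 of them adjusted over the list alone (adjusted p = 1.05e-07, adjusted p = 0.438 with an estimated correlation). H2-Ab1 stood at 1771 ± 513 CPM against 1171 ± 361 CPM (0.60 ± 0.26). Interferon gamma response genes were higher, 20 of 28 with a median of 0.22 (adjusted p = 0.000477, adjusted p = 0.675 with an estimated correlation), and type I interferon response genes 15 of 18 with a median of 0.20 (adjusted p = 0.00152, adjusted p = 0.631 with an estimated correlation). For mean log2 levels of the samples, the exact permutation p was 0.0571 for MHC class II, 0.257 for interferon gamma response and 0.171 for type I interferon response. Beside these changes in monocytes, the mean log2 level of macrophage transcripts was 0.56 higher (exact permutation p = 0.114), that of dissociation and immediate early genes 0.43 higher (exact permutation p = 0.0286) and that of neutrophil transcripts 0.60 lower (exact permutation p = 0.0857). Isg15 stood at 170 ± 66.1 CPM against 74.5 ± 25.1 CPM (1.19 ± 0.30, edgeR adjusted p = 0.344). In macrophages alone, interferon gamma response genes were lower, 28 of 30 with a median of -0.24 (adjusted p = 0.00166, adjusted p = 0.877 with an estimated correlation), as were MHC class I genes, 18 of 18 with a median of -0.20 (adjusted p = 0.00166, adjusted p = 0.838 with an estimated correlation). Between samples, the exact permutation p was 0.571 for the former and 0.429 for the latter. For interferon gamma response, the mean log2 level was 5.35 in AG120 4 and 6.35 to 6.67 in the other AG120 samples. Vehicle samples lay at 5.97 to 6.85. The effects in both cell types were not shown to differ: the difference was 0.52 for interferon gamma response (exact permutation p = 0.114), 0.43 for MHC class I (0.0857) and 0.60 for MHC class II (0.114), with a lowest adjusted p of 0.524 in 23 exact permutation tests. Monocytes alone gave 2 called genes, Fkbp5 higher and Bhlhe40 lower.

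Over all cells, chaperone genes had positive log2 fold changes and immediate early genes of the same list went both ways, a difference that was not tested. Hspa8 stood at 1399 ± 159 CPM in AG120 and 901 ± 194 CPM in Vehicle (0.63 ± 0.16, 4 of 4 AG120 samples above every Vehicle sample), Hsph1 at 0.82 ± 0.20, Hspa1a at 0.88 ± 0.21 and Dnajb1 at 0.37 ± 0.10. Junb stood at -0.31, Egr1 at -0.37, Ier2 at -0.24, Fos at 0.04 and Fosb at 0.46. Fkbp5, a gene that glucocorticoids induce, stood at 36.2 ± 6.87 CPM against 19.2 ± 2.49 CPM (0.91 ± 0.15, edgeR adjusted p = 0.477), with 4 of 4 AG120 samples above every Vehicle sample. Other genes that glucocorticoids induce stood at -0.17 ± 0.13 (Per1) and 0.22 ± 0.23 (Tsc22d3). None of these genes passed over all cells.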
